A study of Mus musculus with 18 samples.

How the data were processed

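The series holds 18 one-colour oligonucleotide arrays of mouse brain RNA. Male C57BL/6J mice of 10.5 weeks were either left undefeated or exposed to social defeat by an aggressor, and defeated mice were classed as susceptible or unsusceptible. The design text speaks of avoidance scores that were alike among the pools of a condition. Tissue of the nucleus accumbens (NAc) and of the ventral tegmental area (VTA) was pooled from 4 animals per array, and each of the 6 combinations of behaviour group and structure has 3 pools. Per the labels' protocols, RNA was extracted with a kit, and total RNA was amplified linearly and labelled with biotin. The design text states that all arrays were run at one time, so no scan or slide batch was modelled.

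The per-sample tables deposited by the authors hold 1 intensity per probe on a linear scale, between 61.9 and 73427.2, with no background column and no detection p-value. The scanner software and any background step applied before these values are not given in the sources used here. The table of the whole series deposited by the authors also holds intensity values. The submitters' processing notes name affy, without a version. Each column of that table has the same maximum, 71810.09, which equals the mean of the 18 scanner maxima (71810.1), and the rank correlation with the scanner values of the same array was 1. Its column medians lie between 170.44 and 170.63. These values have the form of a quantile normalization over all 18 arrays on the linear scale, and their median absolute difference from the values computed here was 0.0109 log2 units. That table has 3949 missing values, so it was used only as an alternative.

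Of 44547 probes per array, 42 were empty on every array and 44505 were tested. Scanner intensities were taken to log2 and quantile normalized over the 18 arrays with limma 3.58.1 in R 4.3.3. Without background subtraction, a log2 change understates the change of a dim probe. A probe with a mean below the median probe mean of 7.39 log2 units is called dim. Gene names come from the platform table. It gives 1 gene for 28482 probes, several genes for 11 and none for 16012, and the named probes cover 17274 genes. The Entrez identifiers of 28427 probes were found in the RefSeq table of the mouse reference assembly, and no symbol changed. A probe without a listed gene is unnamed here. No coordinates are printed because no genome build was named for the probes.

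One limma model with a mean per group was fitted to all 18 arrays, so that the 6 groups share one estimate of the spread, with 12 residual and 11.7 prior degrees of freedom and an intensity trend in the prior. The contrasts were susceptible against control, unsusceptible against control and susceptible against unsusceptible in each structure, the difference of the first 2 between the structures, and VTA against NAc. Tests were two-sided, and Benjamini-Hochberg adjustment ran over all probes within a contrast with a threshold of 0.05. The number of arrays limits the precision, since every group mean rests on 3 pools. The error of a log2 change is the model's standard error, and group levels are given as mean ± SD of 3 pools.

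Before the data were examined, 26 gene lists of 671 entries were fixed: immediate early genes, dopamine, medium spiny, serotonin and cortical excitatory neuron markers, oligodendrocyte, astrocyte, microglia, choroid plexus, blood and endothelial markers, hypothalamic peptides, potassium channels, sodium, calcium and HCN channels, glutamate receptors, GABA receptors, neuropeptides and granins, neurotrophin signalling, glucocorticoid-responsive genes, interferon and inflammation genes, oxidative phosphorylation, ribosomal proteins, heat shock chaperones, cholesterol synthesis, synaptic vesicle genes and chromatin regulators. Each gene was represented by its brightest probe. Lists were tested with limma's fry, which asks whether the members move one way on balance, or, in its mixed form, whether they change in either direction. Neither form compares a list with other genes. Adjustment ran over the 26 lists within a contrast. The competitive test camera was run with a preset correlation of 0.01 and with an estimated correlation. Members past the threshold are counted both adjusted over the list alone and over all probes. The study is known to have picked potassium channels and Bdnf from these samples. A list of neutrophil granule markers was added after S100a8 and Lcn2 had been seen.

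Genes were named by a rule fixed in advance. In each contrast and direction it takes up to 10 genes past the threshold by size of change, filled to 8 with the bright named probes of smallest p, and the 10 largest each way for VTA against NAc. It adds up to 4 members of smallest p from each list past the threshold, and Bdnf, Th, Fosb, Fos, Drd1, Drd2, Kcnf1, Kcnh3, Kcnq3, Fkbp5, Ttr and Mbp in every contrast.

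The code was tested on simulated data with known changes at the real arrays' means and spread over 44505 probes. Changes of 0.5 log2 units were recovered for 73.1% of probes in NAc susceptible against control, 83.6% in NAc unsusceptible against control, and 70.1% in both VTA comparisons. Changes of 1 and 2 log2 units were recovered for 100% of probes in all 4 comparisons. Each simulated comparison held 67 changed probes at 0.5, 67 at 1 and 66 at 2 log2 units. So many true changes ease the adjusted threshold. The real data called 29 and 1 probes in NAc susceptible and unsusceptible against control, and 1 and 3 in the VTA. The recovered shares therefore do not show that changes of these sizes were absent where no call was made. False calls numbered 11 of 193, 9 of 198, 5 of 185 and 8 of 188 in the same order of comparisons. A shift of 0.1 log2 units put on the potassium channel list among 17274 genes was found in both NAc comparisons and in VTA unsusceptible against control, but not in VTA susceptible against control. In VTA unsusceptible against control 1 of the 2 lists called was false.

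The alternatives fixed in advance were median scaling, quantile normalization of each structure alone, an offset of 50 before log2, bright probes only, the table of the whole series, each structure fitted alone, no intensity trend, array weights, the replicate number as a block, a random block of behaviour and number, both forms of camera, the mean over all probes of a gene, and leaving out each array in turn. After the data were seen, a fit without 3 arrays that stood apart and fits of the VTA arrays with dopamine or cortical marker levels as a covariate were added, and the responses were compared again with the control pools parted between them. Splits of the samples into other groups of the same sizes were refitted in the same way.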

Results

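Gene expression was measured in the nucleus accumbens (NAc) and the ventral tegmental area (VTA) of undefeated control mice and of mice that had gone through social defeat and were classed as susceptible or unsusceptible by their later avoidance. The VTA holds the midbrain dopamine neurons, and the NAc, in the ventral striatum, is one of their main targets. Each array carried RNA pooled from 4 male mice, and 3 pools represented each of the 6 groups. Every p-value below therefore measures the spread between pools, not between animals. Median scanner intensities of the 18 arrays ran from 148.3 to 253.1.

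The arrays separated by structure along the first principal component, which held 64.4% of the variance. No array pair had identical values. Correlations within a structure were at least 0.985, and those between structures reached 0.973. A few arrays stood apart from their group. NAc unsusceptible pool 3 was the brightest array, with a median intensity of 253.1 and an upper quartile of 833.2 before normalization. NAc control pool 3 had the lowest upper quartile, 287.3, and the lowest array weight, 0.587. VTA unsusceptible pool 3 lay nearer to the NAc arrays on the first component, at 26.6, where the other VTA arrays lay between 36.4 and 41.9.

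**Figure D1:**
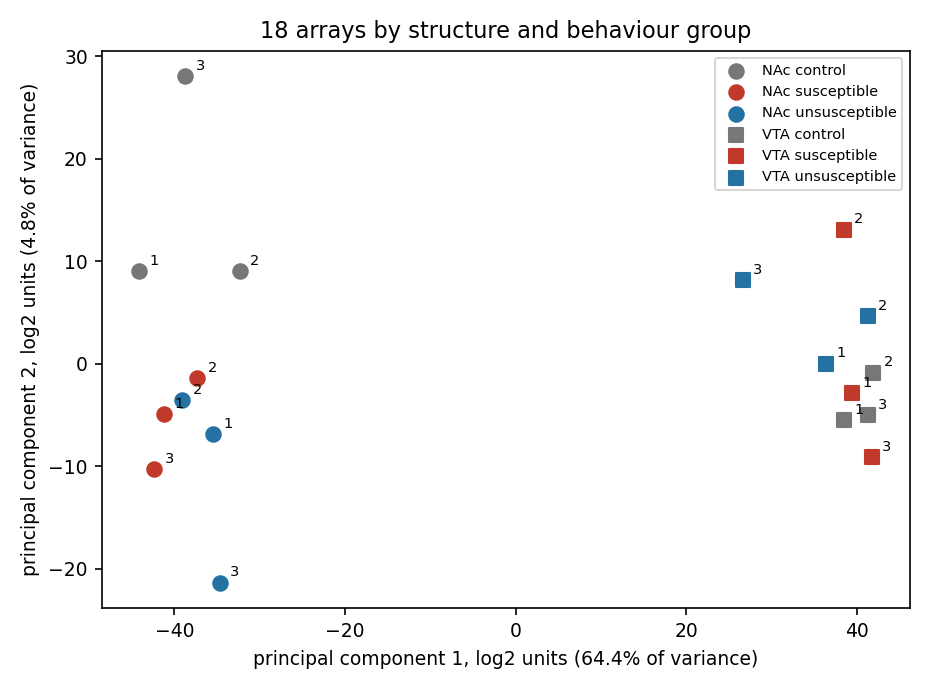
Principal components 1 and 2 of the 18 arrays, in log2 units, with 1 point per pool, coloured by behaviour group, circles for NAc and squares for VTA, and replicate numbers beside the points. The structures separate on the component holding 64.4% of the variance, while NAc control pool 3 (28.0) and NAc unsusceptible pool 3 (-21.3) mark the ends of the component holding 4.81%.

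Marker genes were compared between the structures to check the structure labels. Genes of dopamine neurons were far higher in the VTA, led by the dopamine transporter gene Slc6a3, which was higher by 6.36 ± 0.24 log2 units (SE, 9 against 9 pools, adjusted p 8.19e-17). The vesicular monoamine transporter Slc18a2 (5.58), tyrosine hydroxylase Th (4.24) and aromatic amino acid decarboxylase Ddc (3.83) followed, with all 9 VTA pools above all NAc pools. Genes of striatal medium spiny neurons were far lower in the VTA, among them Drd1 (-4.81 ± 0.10), the phosphoprotein gene Ppp1r1b (-4.21), Rgs9 (-4.08) and Arpp21 (-4.96). The largest single difference was that of the thyroid hormone-binding protein gene Crym (-6.55 ± 0.12, adjusted p 6.39e-23). Other genes high in the VTA were the vesicular glutamate transporter Slc17a6 (4.53), C1ql2 (4.20), Aldh1a1 (4.12), Cbln1 (3.99), En1 (3.88) and the serotonin synthesis gene Tph2 (3.82, in 8 of 9 pools). Egr3 (-4.53), Rin1 (-4.11), Itpka (-3.97), Npy (-3.90) and Car12 (-3.80) were low there. In total 12482 of 44505 probes, 28.0%, differed between the structures, 6483 higher and 5999 lower in the VTA.

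By list, 22 of 26 moved one way between the structures, 11 higher and 11 lower in the VTA, and 7 of these calls were kept with an estimated correlation. Among the 7, all 19 measured medium spiny markers fell (mean -2.87), and immediate early genes fell in 15 of 25 with 1 higher (-0.815; Egr4 -3.79, Egr1 -2.47, Homer1 -2.31). Glutamate receptors (-0.323; Grin2b -1.39, Gria2 -1.35) and microglia markers (-0.286; Cx3cr1 -0.62) were lower too. Astrocyte markers rose in 13 of 17 with 2 lower (0.633; S100b 1.61, Atp1b2 1.53, Aqp4 1.48), cholesterol synthesis genes in 16 of 18 (0.565; Cyp51 0.94, Msmo1 0.80) and heat shock chaperones in 12 of 20 with 1 lower (0.243; Bag3 0.88, Hspa4l 0.81).

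The other 15 calls were lost with an estimated correlation. Dopamine neuron markers were higher in 18 of 19 with 1 lower (mean 2.85), serotonin neuron markers in 7 of 7 (1.56) and oligodendrocyte markers in 18 of 19 (0.844; Trf 1.49, Fa2h 1.25, Qdpr 1.06). Their adjusted p values with an estimated correlation were 0.151, 0.106 and 0.0796. Choroid plexus markers (0.299; Otx2 1.49), hypothalamic peptides (0.390; Ghrh 1.20, Hcrt 1.80), interferon and inflammation genes (0.147; Ifit2 0.80), oxidative phosphorylation genes (0.0817; Ndufb8 0.46) and synaptic vesicle genes (0.0608; Vamp1 2.54) were higher. With an estimated correlation these had an adjusted p of 0.387, 0.698, 0.447, 0.584 and 0.779. The difference of the hypothalamic list rested on the defeated pools. In control pools it lay at 7.80 ± 0.01 in the VTA and 7.82 ± 0.19 in the NAc, and Hcrt at 7.84 and 7.81. Cortical excitatory markers (-0.657; Slc17a7 -2.98, Fezf2 -2.42), GABA receptors (-0.398, median 0.0101; Gabrd -3.20) and ribosomal proteins (-0.0856; Rps2 -0.60) were lower, each with an adjusted p of 0.303 with an estimated correlation. Potassium channels split, with 12 higher and 21 lower of 54 (-0.285; Kcnh3 -2.53, Kcnh1 -2.38, Kcnj4 -2.23), or 24 lower adjusted over the list alone (adjusted p = 0.0796 with an estimated correlation).

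Neuropeptides and granins had a mean of -0.468 with 8 higher and 8 lower of 21 (Pdyn -3.40, Penk -3.29), while their median was 0.0515 (adjusted p = 0.325 with an estimated correlation). Sodium, calcium and HCN channels (-0.0509; Cacna2d3 -1.63, Cacna1g 1.90) and neurotrophin signalling genes (-0.0381; Map2k1 -0.73, Bdnf 0.56) moved down on balance, with an adjusted p of 0.151 and 0.428 with an estimated correlation. Blood markers (0.218, adjusted p 0.101), endothelial markers (0.0764, adjusted p 0.101), glucocorticoid-responsive genes (-0.0322, adjusted p 0.205) and chromatin regulators (-0.0267, adjusted p 0.354) did not pass, and the last pair had medians above 0 (0.0778 and 0.0265).

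The first question of the study was which genes differ between susceptible and control mice. In the NAc, red cell transcripts and the transcripts of Lcn2, S100a8 and S100a9 were higher in the susceptible pools. The beta globin gene Hbb-bt rose by 1.85 ± 0.25 log2 units (3.61-fold, adjusted p 0.00524), Hbb-bs by 1.76 ± 0.26 (3.38-fold) and the alpha globin gene Hba-a1 by 1.28 ± 0.21 (2.42-fold), in 3 of 3 pools each. The iron-siderophore binding protein lipocalin 2, Lcn2, rose by at least 1.63 ± 0.30, from 7.19 ± 0.10 in control to 8.82 ± 0.26 in susceptible pools (SD, n = 3), since a control level below the median probe, as also for S100a8 and S100a9, was not shown to lie above background. The neutrophil calprotectin subunits S100a9 (1.38 ± 0.26, adjusted p 0.0389) and S100a8 (1.35 ± 0.26, adjusted p 0.0432) rose with it. Both lost their call with an offset of 50 (adjusted p 0.0569 and 0.0624) and among bright probes (0.0702 and 0.0761), as did Lcn2 among bright probes (0.0664), and S100a8 also with array weights (0.0638) or no intensity trend (0.0536). With 1 array left out, Lcn2 kept its call only without control pool 2, S100a9 without control pool 2 or susceptible pool 2, and S100a8 without susceptible pool 2, and the largest adjusted p, without susceptible pool 3, was 0.318, 0.479 and 0.479. Higher values of S100a8 and S100a9 were not particular to susceptible pools. In NAc unsusceptible pools 1, 2 and 3, S100a8 lay at 8.38, 8.03 and 7.55, where the highest NAc control was 7.22. S100a9 lay there at 8.29, 8.05 and 7.48, where the highest NAc control was 7.18.

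Of 29 probes past the threshold in this comparison, 28 were higher and 1 was lower in susceptible pools, each in 3 of 3 pools. They covered 12 genes and 9 unnamed probes, and 12 of the 29 were among the 16 globin probes, which had a median change of 1.35. Adult globin genes are close copies of one another, so the array cannot be relied on to tell them apart. The remaining higher genes were Hbb-b2 (1.22 ± 0.19), Osbpl8, a lipid transfer protein gene (0.87 ± 0.15, adjusted p 0.0225), 9930021J03Rik (0.61 ± 0.11), Bptf, a chromatin remodelling subunit (0.58 ± 0.10), and Sox18, an endothelial transcription factor (0.50), the only one outside the naming rule and chosen after its value was seen. The lower gene was Prpf4, coding for a spliceosome protein (-0.42 ± 0.08, adjusted p 0.0432). Prpf4, Bptf and 9930021J03Rik lost their calls with median scaling (adjusted p 0.865, 0.733 and 0.716) and with the NAc fitted alone (0.128, 0.0924 and 0.0800), and Prpf4 also with array weights (0.0607). The other Osbpl8 probes changed by -0.03 and 0.10, so the probes of this gene disagree. The next lower genes did not pass: Tmem88 (-0.64), Nnat (-0.51, adjusted p 0.133), Itih3 (-0.46), Tsc22d1 (-0.44), the survival factor Bcl2l2 (-0.43, adjusted p 0.0850), the cytochrome oxidase assembly gene Cox16 (-0.36, adjusted p 0.152) and Plpp3 (-0.26).

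The blood list was the only one of 26 that moved in NAc susceptible pools. All 5 measured members were higher, adjusted over the list alone, and 3 over all probes, with a mean change of 1.02 ± 0.193 (SE over genes, adjusted p 0.00538, 3 of 3 pools above all controls) and an adjusted p of 0.0114 with an estimated correlation. Its level was 10.21 ± 0.08 in control and 11.23 ± 0.16 in susceptible pools. The erythroid haem synthesis gene Alas2 (0.83, adjusted p 0.125) and the red cell anion exchanger Slc4a1 (0.35) belong to it. Endothelial markers had a mean of 0.0201 (adjusted p 0.976) and interferon and inflammation genes one of -0.00338 (adjusted p 0.976). Single members of other lists passed adjusted over the list alone. These were Bcl11b among medium spiny markers (0.49), Kcnq5 among potassium channels (0.52), Lcn2 among glucocorticoid-responsive genes, and the astrocyte genes Slc1a3 (-0.30), Ntsr2 (-0.25), Gja1 (-0.17) and Id3 (0.32). Potassium channels had a mean of 0.00175, a median of -0.0457 and a downward test (adjusted p 0.976). Among the fixed genes, Fosb changed by 0.27 ± 0.09 (adjusted p 0.380, 2 of 3 pools), Drd1 by 0.24, Drd2 by 0.20, Ttr by 0.27 ± 0.53, Fkbp5 by 0.15, Bdnf by -0.03, Fos by -0.26 and Kcnf1 by -0.13, none past the threshold.

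The number of probes called depended on single arrays. It was 11 without control pool 1, 143 without control pool 2, 57 without susceptible pool 2, 2 without susceptible pool 3, and 0 without susceptible pool 1 or control pool 3, and 18 among bright probes alone. Without the 3 arrays that stood apart, it was 5 and the blood list had an adjusted p of 0.0568 (mean 0.976).

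**Figure D2:**
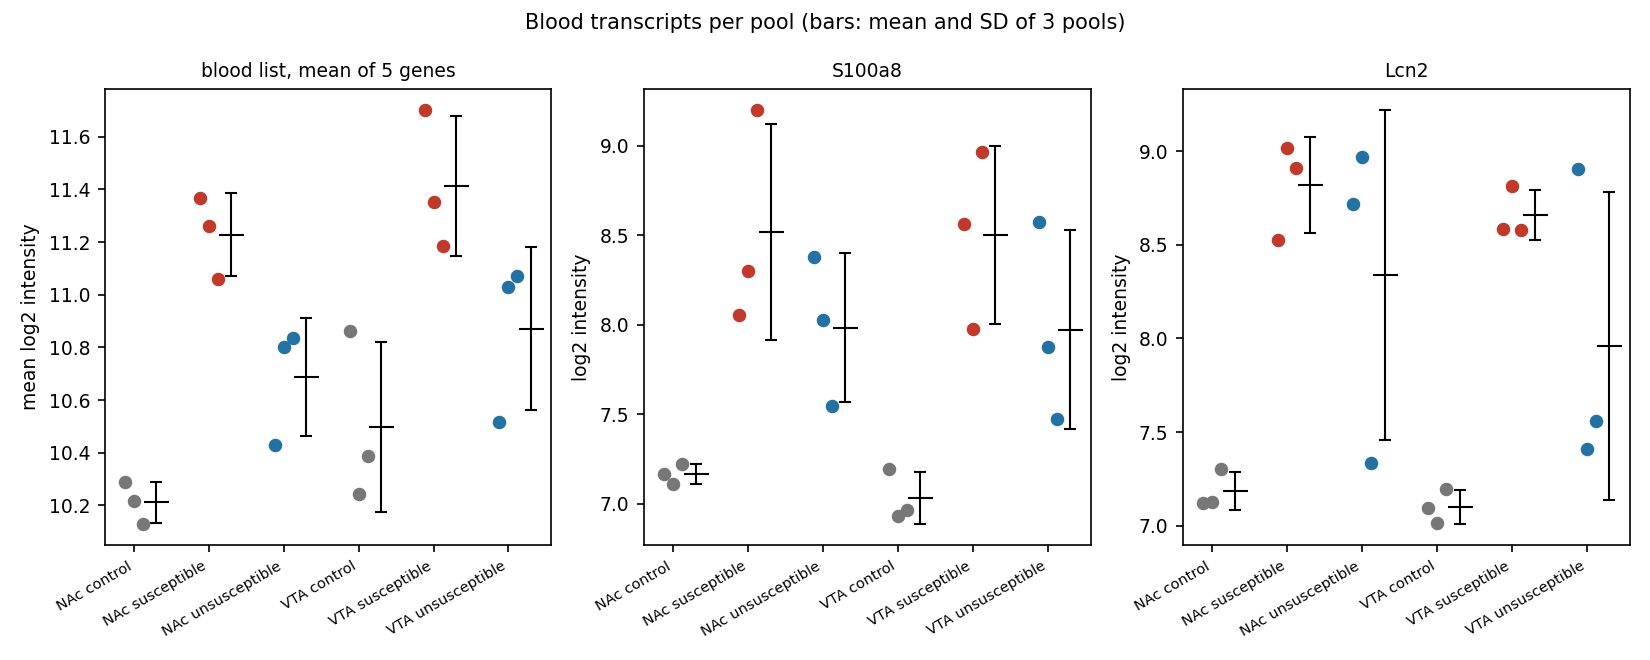
Log2 intensity per pool in the 6 groups is shown for the mean of the 5 blood genes, for S100a8 and for Lcn2. Each pool is 1 point, and bars give the mean and SD of 3 pools. The blood list lies at 10.21 ± 0.08 in NAc control against 11.23 ± 0.16 in NAc susceptible pools, and at 10.50 ± 0.32 against 11.41 ± 0.26 in the VTA.

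In the VTA the same comparison showed higher red cell transcripts. The probe of Hbb-bs with the smallest p rose by 1.32 ± 0.20 log2 units (2.49-fold, adjusted p 0.0409, 3 of 3 pools), from 13.72 ± 0.57 in control to 15.04 ± 0.25 in susceptible pools (SD, n = 3). It was the only 1 of 44505 probes past the threshold. S100a8 (1.47 ± 0.26), Alas2 (1.02 ± 0.19) and Hba-a1 (1.16 ± 0.21) had an adjusted p of 0.0728, Hbb-bt (1.30) one of 0.0903, Lcn2 (1.56 ± 0.30) one of 0.110, Hbb-b2 (0.87) one of 0.369 and S100a9 (1.15) one of 0.438, each higher in 3 of 3 pools. The control levels of Lcn2 (7.10), S100a8 (7.03) and S100a9 (7.25) lay below the median probe. They were not shown to lie above background, so the changes of these genes are lower bounds. An unadjusted p under 0.05 was reached by 1539 probes, below the 2225.25 that chance gives.

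As a group, blood markers rose in the susceptible VTA by 0.915 ± 0.153 (adjusted p 0.0123, 3 of 3 pools, adjusted p 0.00459 with an estimated correlation), with 5 of 5 members higher adjusted over the list alone and 0 over all probes. The globin probes had a median change of 1.18. Endothelial markers averaged 0.0756 (adjusted p 0.887). Lists of other cell types did not pass by fry, while camera called 3 of 26 lists with the preset and 1 with an estimated correlation. Oligodendrocyte markers averaged -0.167 with 19 of 19 members below 0 (adjusted p 0.797), serotonin neuron markers -0.519 (adjusted p 0.797; Tph2 -1.43, Slc6a4 -1.28), dopamine neuron markers -0.115 and potassium channels 0.0196 (adjusted p 0.878). Part of the serotonin difference rested on control pool 2, with a list level of 10.37 where control pools 1 and 3 lay at 9.61 and 9.55. The genes of smallest p among those lower were Mbp by its second probe (-0.53), the splicing factor Tra2a (-0.42), Llph (-0.42), the mitochondrial import gene Timm23 (-0.40), Ccdc115 (-0.35), Lrrc20 (-0.35), Spag6l (-0.33) and the actin gene Actb (-0.28), all with an adjusted p of 1. The orexin precursor gene Hcrt had a difference of 1.74 (adjusted p 1), resting on susceptible pool 3 at 12.52, where controls lay between 7.76 and 7.88. Drd1 changed by 0.22, Kcnf1 by 0.19, Fkbp5 by 0.15, Kcnh3 by 0.14, Bdnf by 0.09, Th by -0.04 and Drd2 by -0.20, none past the threshold.

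The single call was lost without susceptible pools 1 or 2 or control pools 2 or 3, while the count was 15 without control pool 1, 2 without susceptible pool 2 (S100a8 and S100a9, adjusted p 0.0388 each), 2 without susceptible pool 3, 11 after median scaling and 13 with array weights, and 0 with bright probes alone, the VTA fitted alone or no intensity trend. The blood list had an adjusted p of 0.0763, 0.0813 and 0.0630 without susceptible pool 1, control pool 2 and control pool 3, and 0.0729 after median scaling.

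The next question was which genes differ between unsusceptible and control mice. In the NAc, 1 probe passed. It belongs to Osbpl8 and rose by 1.02 ± 0.15 log2 units (2.02-fold, adjusted p 0.0336, 3 of 3 pools), from 8.68 ± 0.17 in control to 9.70 ± 0.02 in unsusceptible pools (SD, n = 3). The same probe, number 104590286, rose in NAc susceptible pools, while the other probes of the gene changed by 0.04 and 0.10. Many genes came close, with an adjusted p of 0.0615 and the same direction in 3 of 3 pools. On the higher side stood the transcriptional repressor Zbtb33 (0.74), Sec22c (0.69), Arglu1 (0.61), Trim35 (0.58), Bclaf3 (0.57), the centriolar satellite gene Pcm1 (0.55) and DNA ligase Lig1 (0.45). On the lower side stood Msx3 (-0.81), the clock repressor Nr1d2 (-0.74), the early endosome gene Rab5a (-0.73), Zfp207 (-0.73), Mboat7 (-0.56), Pkp4 (-0.53), the RNA helicase Ddx27 (-0.50) and Gatb (-0.50). An unadjusted p under 0.05 was found for 5096 probes, 2608 higher and 2488 lower, against 2225.25 by chance.

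No list moved one way in NAc unsusceptible pools by fry with quantile normalization, while 1 of 26 did so at an unadjusted p under 0.05, and camera called 1 with the preset and 0 with an estimated correlation. Oxidative phosphorylation genes changed in either direction (mixed adjusted p 0.0306), with 7 higher and 12 lower of 64 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The complex I genes Ndufa10 (-0.37) and Ndufv1 (-0.21) and the ATP synthase gene Atp5g1 (-0.27) were among the lower, and Ndufb5 (0.29), Ndufb2 (0.37) and Atp5k (0.41) among the higher. The interferon and inflammation list had 3 higher members of 25 adjusted over the list alone, Ifit3 (0.64), Isg15 (0.48) and Psmb9 (0.41), with a mean of 0.117 (adjusted p 0.673). Blood markers had 3 higher members of 5 adjusted over the list alone and a mean of 0.477 (adjusted p 0.673). Adjusted over the list alone, Cacna2d1 (-0.53), Cacna2d2 (-0.38) and Scn2b (-0.28) were lower among sodium and calcium channel genes, Cplx2 (-0.62) among synaptic vesicle genes, and Hspa5 (0.43), Scg3 (0.52), Neurod6 (0.72), Sparcl1 (0.41) and Lcn2 (at least 1.15) were higher in their lists. Fosb changed by 0.30 (adjusted p 0.179, 3 of 3 pools), Ttr by 0.64 ± 0.53, Drd1 by 0.20, Fkbp5 by 0.19, Kcnq3 by -0.20, Kcnf1 by -0.11 and Drd2 by 0.07, none past the threshold with quantile normalization.

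The count in this comparison was 404 without control pool 2, 6 without unsusceptible pool 2, 2 without control pool 1, and 0 without control pool 3 or unsusceptible pool 1 or 3, and it was 2 without the 3 arrays that stood apart. Median scaling gave 1229 probes, 1186 higher and 43 lower, the NAc fitted alone gave 4, and array weights or bright probes alone gave 0. With median scaling 11 lists also passed as higher, namely blood (0.812, adjusted p 0.0409), interferon and inflammation (0.271, adjusted p 0.0270), medium spiny neuron (0.548), astrocyte (0.503), oxidative phosphorylation (0.466), glucocorticoid-responsive (0.460), microglia (0.438), heat shock chaperone (0.429), ribosomal (0.425), choroid plexus (0.338) and potassium channel genes (0.314), as did Fosb (0.84, adjusted p 0.0411) and Fkbp5 (0.72, adjusted p 0.0499). Median scaling levels the medians but not the upper quartiles. These were 833.2 in NAc unsusceptible pool 3 and 287.3 in NAc control pool 3. The calls made only with median scaling cannot be told apart from this difference in scale between arrays.

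In the VTA, genes of myelin and oligodendrocytes were lower in unsusceptible than in control pools. The myelin gene Mobp fell by 0.75 ± 0.12 log2 units (adjusted p 0.0259), from 13.91 ± 0.15 to 13.17 ± 0.28 (SD, n = 3), and a second probe of it fell by 0.65. The myelin oligodendrocyte glycoprotein gene Mog fell by 0.66 ± 0.10 (adjusted p 0.0259), from 12.10 ± 0.09 to 11.45 ± 0.18. These 3 probes, each lower in 3 of 3 pools, were the ones past the threshold, while 3050 had an unadjusted p under 0.05. Mobp has further probes at -0.49, -0.41 and -0.18, and Mbp has probes at -0.77, -0.67 and 0.14. The brightest Mbp probe lay between 15.98 and 16.12 in the VTA, at the top of the scale, where a change cannot be read.

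Oligodendrocyte markers fell as a list, by a mean of -0.364 ± 0.0451 (adjusted p 0.0222, 3 of 3 pools below all controls, adjusted p = 0.0671 with an estimated correlation), and by -0.231 without unsusceptible pool 3 (adjusted p 0.0469). All 19 members were below 0, 15 of them past the threshold adjusted over the list alone and 2 over all probes. Besides Mobp and Mog, the carbonic anhydrase gene Car2 (-0.64, adjusted p 0.0541), the connexin Gjb1 (-0.64, adjusted p 0.285), transferrin Trf (-0.50), Cnp (-0.41) and Fa2h (-0.37) were among the 15. The list lay at 12.03 ± 0.08 in control, 11.87 ± 0.07 in susceptible and 11.67 ± 0.23 in unsusceptible pools. Unsusceptible pool 3, the array that stood apart, was lowest at 11.40. That pool also had the lowest dopamine neuron list, 9.40 against a control level of 11.44 ± 0.16, and the lowest Th, 9.52.

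Potassium channel genes rose as a list by 0.0977 ± 0.0285 (adjusted p 0.0222, 3 of 3 pools above all controls, adjusted p = 0.0671 with an estimated correlation). Of 54 measured channels, 6 were higher adjusted over the list alone and 0 over all probes, 12 were higher and 0 lower at an unadjusted p under 0.05, and 39 lay above 0. The study chose this family on these samples, so the list is not independent evidence of the direction. The 6 were the modulatory subunit Kcnf1 (0.63 ± 0.15, adjusted p 0.430 over all probes, 3 of 3 pools), the BK channel subunit Kcnmb4 (0.61, 2 of 3 pools), the fast-spiking channel Kcnc1 (0.58, 2 of 3 pools), Kcnk4 (0.35, 3 of 3 pools), Kcnc2 (0.34) and Kcnd1 (0.30). Kcnq3 (0.28) and Kcnh3 (0.23) were higher in 3 of 3 pools without passing. Kcnh3 lay below the median probe in both groups, at 7.15 ± 0.04 in control and 7.38 ± 0.05 in unsusceptible pools, and was not shown to lie above background. The list lay at 8.82 ± 0.02 in control, 8.84 ± 0.04 in susceptible and 8.91 ± 0.04 in unsusceptible pools. Dopamine neuron markers averaged -0.804 beside it without passing by fry (adjusted p 0.213), and this mean rested on unsusceptible pool 3, being -0.189 without that pool (adjusted p 0.710) and -1.28 without pool 2 (adjusted p 0.00764).

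**Figure D3:**
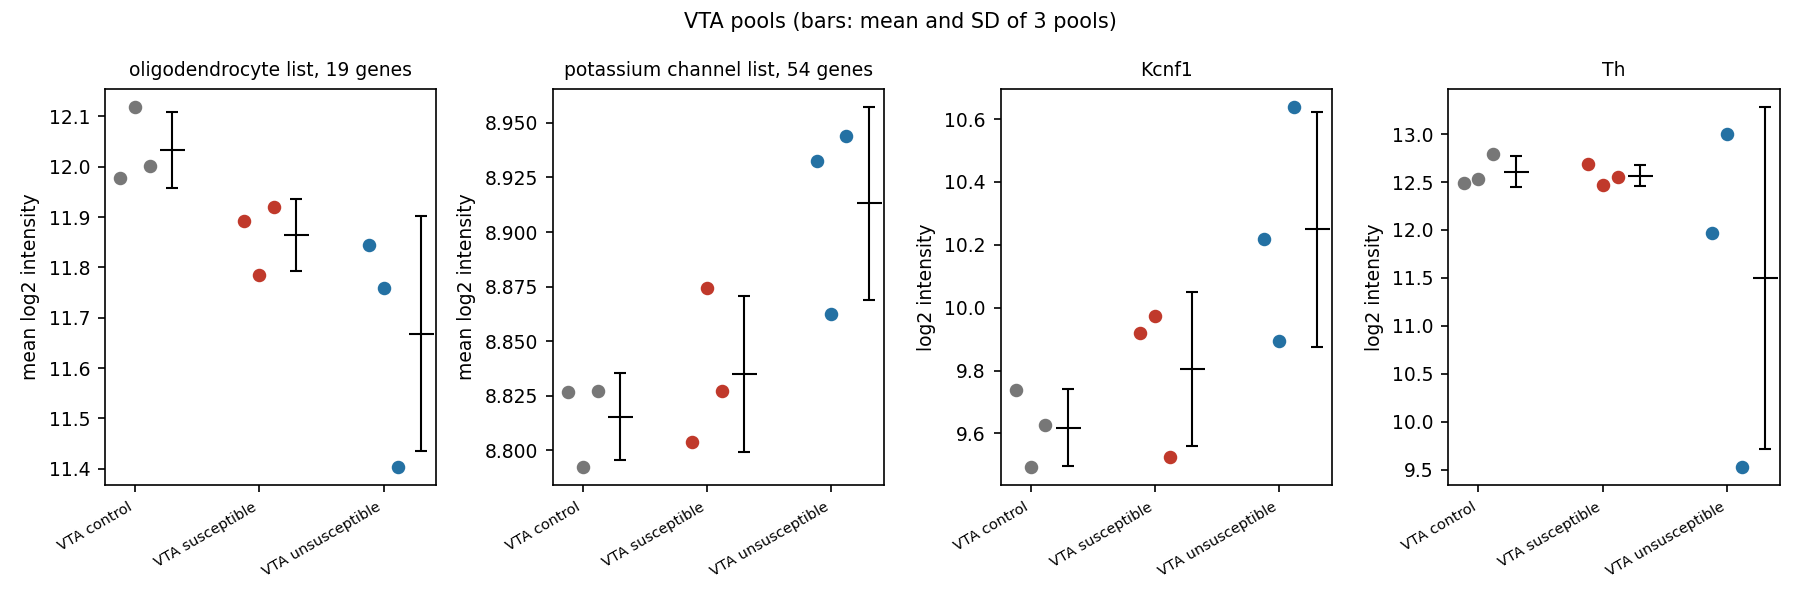
Log2 intensity per VTA pool in the 3 behaviour groups, 1 point per pool, with bars for the mean and SD of 3 pools, for the oligodendrocyte list of 19 genes, the potassium channel list of 54 genes, Kcnf1 and Th. All 3 unsusceptible pools lie below the controls for oligodendrocyte genes and above them for potassium channel genes, and Th is at 9.52 in unsusceptible pool 3.

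Immediate early genes and astrocyte markers changed in either direction in the unsusceptible VTA without passing one way by fry. The mixed form was not rerun with an array left out, so how far it rests on unsusceptible pool 3 is unknown. Among immediate early genes (mixed adjusted p 0.0453), the transcription factors Egr1 (0.59), Egr3 (0.50) and Egr4 (0.43) were higher and Gadd45b (-0.40) lower adjusted over the list alone. These Egr genes were far lower in the VTA than in the NAc. The cortical marker Slc17a7 lay at 9.78, 7.31 and 9.28 in unsusceptible pools 1, 2 and 3, where the highest VTA control was 8.97. Fos lay at 9.02 in control and 9.04 in unsusceptible pools. Tissue from outside the VTA was not tested as a source. Among astrocyte markers (mixed adjusted p 0.0357), the glutamate transporter Slc1a3 (0.39) was higher, and the water channel Aqp4 (-0.48) and S100b (-0.47) were lower. The astrocyte list averaged -0.142 (adjusted p 0.213, or 0.0154 by camera with the preset and 0.249 with an estimated correlation), with 3 of 3 pools below all controls. The oligodendrocyte and potassium channel lists passed in this form too (mixed adjusted p 0.00527 and 0.0453). In this comparison camera called 7 of 26 lists with the preset and 0 with an estimated correlation. Dopamine neuron markers had 17 of 19 members lower adjusted over the list alone, but did not pass as a list by fry (adjusted p 0.213). Slc18a2 (-1.24), Slc6a3 (-1.18), Th (-1.11 ± 0.44, adjusted p 0.611, 2 of 3 pools) and Ddc (-1.03) belong to it. Serotonin neuron markers averaged -0.691 (adjusted p 0.213; Tph2 -2.05, Slc6a4 -1.33), hypothalamic peptides 0.578 (adjusted p 0.213; Hcrt 2.69, Oxt 0.57, Trh 0.44), cortical excitatory markers 0.126 (adjusted p 0.785) and blood markers 0.373 (adjusted p 0.244). Without unsusceptible pool 3 the serotonin mean was -0.233 and the hypothalamic mean 0.335, and without control pool 2 the serotonin mean was -0.428.

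Further genes of small p that did not pass in the unsusceptible VTA were, on the higher side, the postsynaptic gene Nrgn (0.74), guanine deaminase Gda (0.63, adjusted p 0.285), Ccdc134 (0.54), Avpi1 (0.53), the RNA-editing enzyme Adarb1 (0.51, adjusted p 0.183), Asb6 (0.42) and Slc9a8 (0.40). On the lower side they were Pdlim2 (-0.61), the astrocytic phosphoprotein gene Pea15a (-0.50, adjusted p 0.165) and Saraf (-0.43). Fkbp5 changed by 0.29, Drd1 by 0.28, Drd2 by -0.62, Ttr by -0.66, Bdnf by 0.00 and Fosb by 0.00. The Drd2 difference rested mostly on unsusceptible pool 3 at 8.05, where pools 1 and 2 lay at 8.98 and 9.45 and controls at 9.45 ± 0.11. The 3 calls were lost without unsusceptible pool 3 or any control pool, and the count was 6 without unsusceptible pool 1 and 270, 194 higher and 76 lower, without unsusceptible pool 2, and 0 with median scaling, the VTA fitted alone or no intensity trend. The oligodendrocyte list lost its call without control pools 2 (adjusted p 0.137) or 3 (0.0562), the potassium list also without unsusceptible pools 1 (0.0645) or 3 (0.0722), and after median scaling they had an adjusted p of 0.327 and 0.912, with means of -0.443 and 0.0227.

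Susceptible and unsusceptible pools were then compared directly. In the NAc 1 unnamed probe, number 104010026, was higher in susceptible pools by 0.60 ± 0.09 (adjusted p 0.0368, 3 of 3 pools), and the call was lost without any one of the 6 arrays. Genes with higher values that did not pass were Map1a (0.75), Ankrd11 (0.73), Psip1 (0.68), the striatal transcription factor Bcl11b (0.61, adjusted p 0.408), the vesicle calcium sensor Syt1 (0.60), Ddx27 (0.52, adjusted p 0.238), the AMPA receptor gene Gria3 (0.51) and Tnrc6b (0.45). Lower values were found for Cbln1 (-0.72), the interferon-induced gene Ifit3 (-0.55, adjusted p 0.814), Nabp2 (-0.42, adjusted p 0.432), Erap1 (-0.41), Cgn (-0.40), Lig1 (-0.39), Sapcd2 (-0.38) and Pmm2 (-0.32). Blood markers had 4 higher members of 5 adjusted over the list alone and a mean of 0.540 (adjusted p 0.426), and interferon genes a mean of -0.120 (adjusted p 0.426). No list passed by fry, 2 of 26 had an unadjusted p under 0.05, and camera called 5 with the preset and 0 with an estimated correlation.

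In the VTA no probe differed between susceptible and unsusceptible pools by limma, with 2465 at an unadjusted p under 0.05 against 2225.25 by chance, but 139 passed without unsusceptible pool 2. The genes of smallest p all had an adjusted p of 0.871. Higher in susceptible pools were Ucn, a stress peptide gene (1.56 ± 0.41), Lum (0.65), Cstf2 (0.57), Car2 (0.52), Nccrp1 (0.51), Mobp by its second probe (0.42), Pltp (0.42) and Gna12 (0.39). Lower were Rasl11a (-0.74), Gdpd5 (-0.53), the calcium channel Cacna1c (-0.50), Osbpl3 (-0.44), Adarb1 (-0.39), the channel kinase Trpm7 (-0.37), Tpcn1 (-0.34) and Rfk (-0.34). Blood markers averaged 0.542 (adjusted p 0.134, 4 of 5 higher adjusted over the list alone), oligodendrocyte markers 0.197 (adjusted p 0.376, 6 of 19 higher adjusted over the list alone) and potassium channels -0.0781 (adjusted p 0.124; Kcnf1 -0.44). No list passed by fry, 3 of 26 had an unadjusted p under 0.05, and camera called 7 with the preset and 0 with an estimated correlation. The potassium list passed without susceptible pool 2 (-0.0976, adjusted p 0.0329) or unsusceptible pool 2 (-0.103, adjusted p 0.0151), and without the latter dopamine neuron markers (1.16) and glutamate receptors (-0.165) passed too.

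Whether the response to defeat differed between the structures was tested as an interaction. For the susceptible response limma called 0 probes, with 2825 at an unadjusted p under 0.05, and for the unsusceptible response 0 probes, with 4698. For the latter the count was 60 without NAc control pool 2, 53 without VTA unsusceptible pool 2, 1 without NAc control pool 1, and 8 after median scaling. Genes with larger values in the VTA for the unsusceptible response were Zfp207 (0.87), Slc9a8 (0.77, adjusted p 0.119), Mboat7 (0.74), Gatb (0.71), Ndufa10 (0.69) and Slc1a3 (0.61), and those with smaller values Osbpl8 (-1.10, adjusted p 0.174), the ankyrin Ank2 (-1.04), Ankib1 (-0.96), Trim35 (-0.75) and the clathrin heavy chain Cltc (-0.74). For the susceptible response the smallest p values belonged to Dnajc10 (-1.14, adjusted p 0.403), Osbpl8 (-1.09), Zbtb33 (-1.04), Trim35 (-0.72), Bptf (-0.67), Emc4 (0.68) and Tsr2 (0.59). The potassium channel list differed by 0.114 for the unsusceptible response without passing (adjusted p 0.0540), and the blood list by -0.102 for the susceptible response (adjusted p 0.957).

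The responses of susceptible and unsusceptible pools were compared with each other across probes, which are not independent replicates. In the NAc the log2 changes correlated at 0.691, where unchanged groups that share the same controls gave 0.50 over 100 simulations. The covariance was 0.0136 against a simulated 0.00603, a difference of 0.00753, and 72.5% of probes had the same sign against 66.7%. In the VTA the correlation was 0.480 against 0.50 and the covariance difference 0.000805. With median scaling these differences were 0.0212 in the NAc and -0.00339 in the VTA. With the 3 control pools parted between the responses, so that none served both, the mean covariance over the 6 ways to do so was 0.00494 in the NAc (0.00393 to 0.00593), and 8 of 840 assignments of the 9 arrays to groups gave one as large (exact permutation p 0.00952). In the VTA it was 0.00145 (155 of 840, exact permutation p 0.185). The simulations gave all groups the same spread, so part of the excess may still come from the shared controls. The Osbpl8 probe was called in both NAc comparisons.

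**Figure D4:**
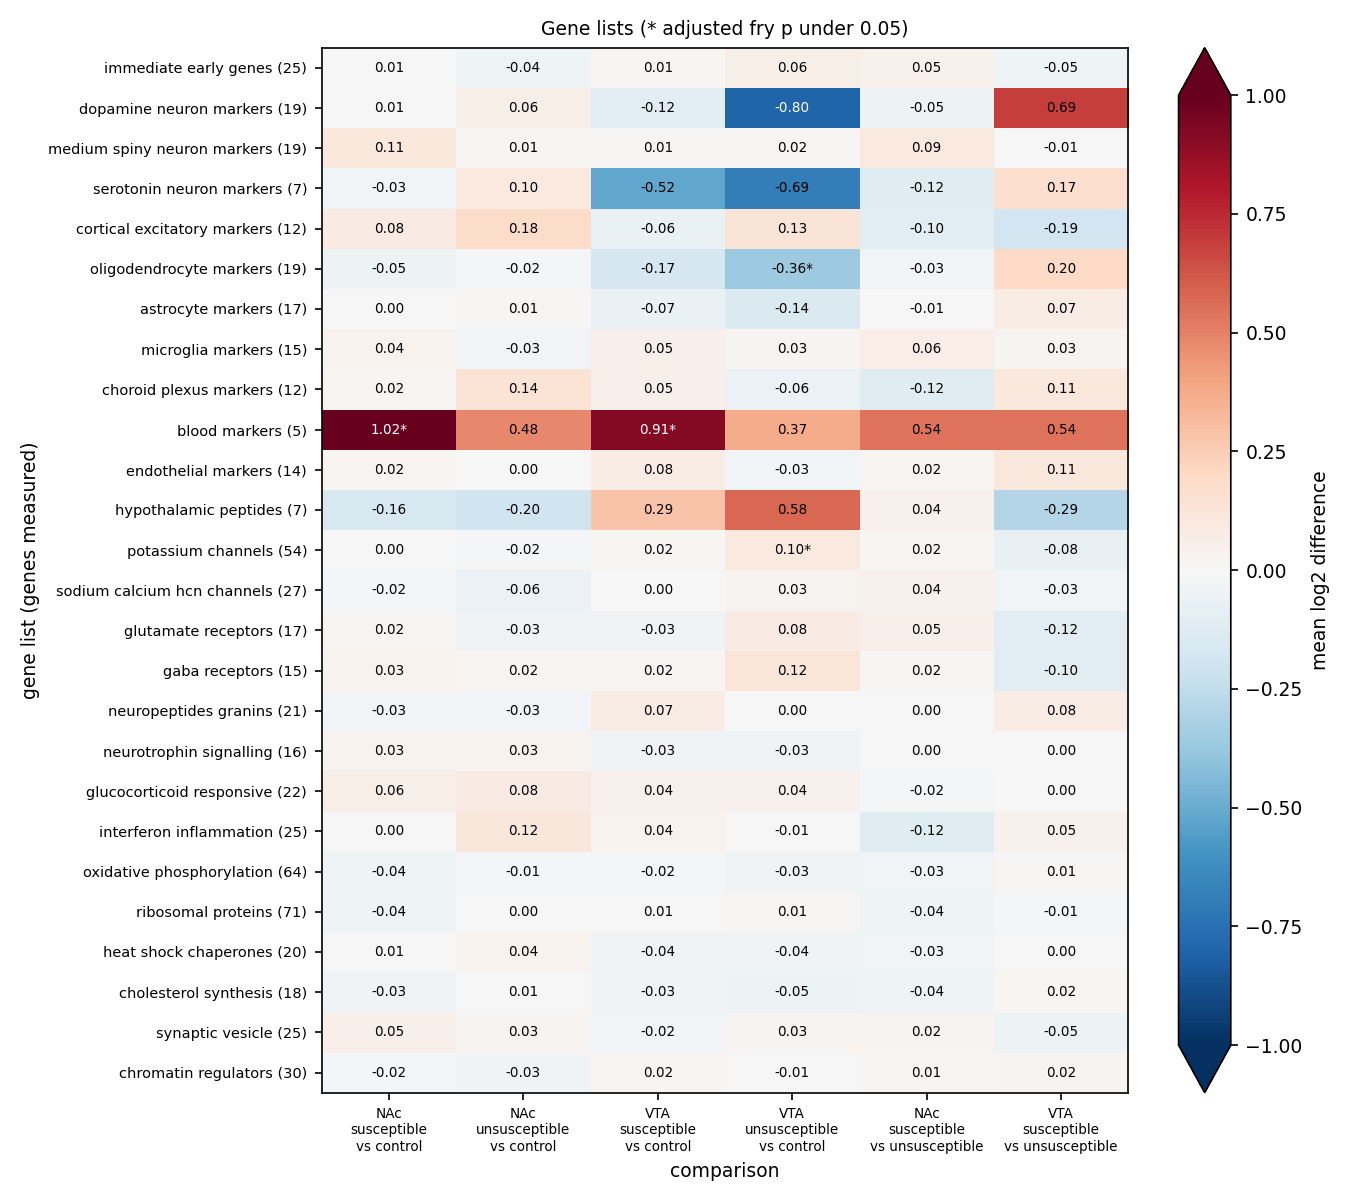
Mean log2 change of each of the 26 gene lists in the behaviour comparisons, as a colour scale with the value printed in each cell and lists past the threshold of 0.05 marked. Blood markers pass in susceptible pools of the NAc (1.02) and the VTA (0.915), and oligodendrocyte markers (-0.364) and potassium channels (0.0977) pass in unsusceptible VTA pools, but not with an estimated correlation (adjusted p 0.0671 for each).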

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

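The dopamine and cortical marker fits, the share of neurons over glia and the vessel tissue test were chosen only after the results they bear on had been seen, as were the list of neutrophil granule markers and the parting of the control pools.

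For the unsusceptible response, 4 lists differed between the structures by a test of the difference itself when members in either direction were counted, each with a mixed adjusted p of 0.0308. Among astrocyte markers Slc1a3 (0.61) was higher in the VTA response, and Gfap (-0.90), Glul (-0.64), Sparcl1 (-0.50) and Id3 (-0.39) were lower, adjusted over the list alone. Among glutamate receptors these were Grin2b (0.78), Gria1 (0.52) and Gria4 (-0.54), among oxidative phosphorylation genes Ndufa10 (0.69), and among heat shock chaperones Hspa4l (-0.43), Stip1 (-0.38) and Hspa5 (-0.51). The mixed form was not rerun with an array left out or under the other alternatives. One way on balance none of the 26 lists passed by fry, while 5 had an unadjusted p under 0.05, and camera called 5 with the preset and 0 with an estimated correlation. With a real count of 0 probes for either response, each of the 100 drawn splits reaches it (100 of 100), so the splits decide nothing there. The highest gave 21 for the susceptible and 25 for the unsusceptible response.

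The first pattern weighed is the higher potassium channel list in VTA unsusceptible pools (0.0977). The single pool low in dopamine transcripts is argued against as the whole cause, since the mean without it was 0.0821, although the adjusted p was then 0.0722, and so are the dimmest members, since those above the median probe gave 0.118. In the 9 VTA arrays alone the call was already lost (adjusted p 0.139), and with dopamine or cortical marker levels as a covariate, which follow the groups in part, the mean was 0.0719 and 0.0801 (adjusted p 0.461 and 0.348). These values argue against less dopamine area or added cortical tissue as the whole cause only, their spread is over genes and not arrays, and a part stays open, as does the normalization, since median scaling gave 0.0227 (adjusted p 0.912). A higher share of neurons over glia cannot be told apart from a channel change, because other neuronal genes averaged 0.0259, lower by 0.0718 ± 0.0398, while oligodendrocyte (-0.364) and astrocyte markers (-0.142) lay lower in 3 of 3 pools, and a biological response of the unsusceptible group may also remain.

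The next pattern is the higher blood transcripts in susceptible pools of both structures. The labels do not say whether NAc and VTA pools came from the same mice, so the structures may not be independent. From pool 1 to 3 the blood list rose in unsusceptible pools, from 10.43 to 10.83 (NAc) and 10.51 to 11.07 (VTA). In susceptible pools it fell, from 11.37 to 11.06 and from 11.70 to 11.18. Control pools 2 and 3 ranked differently, at 10.22 and 10.13 in the NAc and 10.24 and 10.39 in the VTA. A single pool is argued against as the whole cause, since the smallest list mean with 1 pool left out was 0.770. Yet the VTA call was lost in 3 of 6 such fits, with an adjusted p of up to 0.0813. More vessel tissue is also argued against as the whole cause, since endothelial markers averaged 0.0201 ± 0.0458 in the NAc and 0.0756 ± 0.0381 in the VTA (SE over genes). A part stays open, since the endothelial gene Sox18 was among the NAc calls (0.50). Whether red cells came without white cells cannot be told apart, because the neutrophil granule markers averaged 0.106 ± 0.0842 in the NAc and 0.128 ± 0.0684 in the VTA, with 12 of 17 genes dim, and without S100a9, already seen to rise, they averaged 0.0265 ± 0.0284 and 0.0639 ± 0.0257. S100a8 did not follow the blood list from pool to pool within the defeated groups. In unsusceptible pools 1, 2 and 3 it fell, at 8.38, 8.03 and 7.55 in the NAc and 8.57, 7.87 and 7.47 in the VTA. In susceptible pools it lay at 8.05, 8.30 and 9.20 in the NAc and 8.56, 7.98 and 8.96 in the VTA. Blood left in the tissue at dissection may differ between groups and was not tested, and neither was a change of the blood itself after defeat.

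The last pattern is the shared change of susceptible and unsusceptible NAc pools against control. Without the array with the lowest upper quartile, control pool 3, the covariance was 0.0144 where simulated unchanged groups gave 0.00862, an excess of 0.00581 against 0.00753 with it. The simulation gave all groups the same spread, while NAc control pools 1, 2 and 3 had array weights of 0.807, 0.923 and 0.587. Its value may be too low for such controls, so it cannot decide whether control pool 3 is the whole source. Probes designed from clones had 2.11 times the covariance of probes designed from RefSeq transcripts averaged over 10 brightness bins, but were higher in only 7 of the 10. The clone probes included bright Hbb-bs probes, and globin probes were not removed. Globin probes had a median change of 1.35 in susceptible and 0.589 in unsusceptible NAc pools. So the ratio may reflect blood in part, and a technical difference between probe types may contribute but was not shown. The control pools used in both responses are argued against as the whole source, since the mean covariance with these pools parted was 0.00494 (exact permutation p 0.00952). A part from them, a technical difference of all controls from all defeated pools, and a biological response to defeat itself stay open.

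The splits of the same 6 pools, with the real one among the 10, were counted for each comparison, and 10 are too few for a share under 0.05. For probes, as many as the real count came from 2 splits, the real one included, for NAc susceptible against control (real 29, highest other 85), 3 for NAc unsusceptible against control (1, 16), 2 for VTA susceptible against control (1, 9), 3 for VTA unsusceptible against control (3, 76), 1 for NAc susceptible against unsusceptible (1, 0) and 10 in the VTA (0, 2). For lists they came, in the same order, from 3 (1, 1), 10 (0, 2), 1 (1, 0), 1 (2, 1), 10 (0, 0) and 10 (0, 2). The 85 probes set control 1 with susceptible 1 and 3 apart, the 76 control 1 with unsusceptible 1 and 3, the 16 controls 1 and 2 with unsusceptible 2, and the 9 controls 1 and 3 with susceptible 3. Marker levels went with some of these splits, in lists picked from many after the splits were seen. For the 85, the NAc medium spiny list lay at 12.49, 12.33 and 12.41 in the pools set apart, against 12.045, 11.98 and 12.09. For the 76, the VTA dopamine list lay at 11.30, 10.92 and 9.40, against 11.41, 11.62 and 11.58. For the 16, the NAc cortical list lay at 8.88, 9.44 and 9.25, against 9.75, 9.60 and 9.77. The counts may come from such a structure of the pools other than their groups, or from noise. Whether such counts exceed what noise among 6 pools gives was not tested. Where the real count is 0, every split reaches it, and the 10 of 10 say nothing. For VTA against NAc, 1 of 100 splits, the real one, reached 12482 probes, and the highest other gave 8073. A share of 1 of 100 is the smallest these splits can give, so they make chance unlikely there but do not exclude it.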

How the results depend on the processing

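The fit without the 3 arrays that stood apart and the fits with a covariate were chosen after seeing the data. Unless stated otherwise, the cause was not tested.

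Median scaling gave 1229 probes in NAc unsusceptible against control, 11 in VTA susceptible against control, 0 in VTA unsusceptible against control and in NAc susceptible against unsusceptible, and 8 for the unsusceptible difference between structures. It gave 12 list calls where 4 were made, 11 of them in NAc unsusceptible against control and 1 for NAc susceptible blood, with the VTA blood list at 0.931 (adjusted p 0.0729), the oligodendrocyte list at -0.443 (0.327) and the potassium list at 0.0227 (0.912). Because it leaves the upper quartiles of the arrays unequal, the 1229 probes and 11 lists cannot be told apart from a difference in scale. The excess covariance of the responses was 0.0212 in the NAc and turned to -0.00339 in the VTA.

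Bright probes alone gave 18 in NAc susceptible against control and 0 in NAc unsusceptible and VTA susceptible against control, with an excess covariance of 0.0138 and 0.00128 in the NAc and the VTA. Each structure fitted alone gave 4 in NAc unsusceptible against control and 0 in NAc susceptible against unsusceptible and in both VTA comparisons with control. Without an intensity trend both VTA comparisons with control gave 0. Array weights gave 0 in NAc unsusceptible and 13 in VTA susceptible against control.

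The replicate block, which takes the replicate number as shared by arrays, gave 79 and 203 probes in NAc susceptible and unsusceptible against control, 0 and 7 in the VTA, and 7 and 2 for the differences between structures. Of 45 array pairs of one number, 9 correlated above 0.1 after group means were removed, with a median of 0.0451 and a range from -0.0451 to 0.198, and 16 of 18 arrays were closest on average to their own number. The labels give no pairing, so the block was not used.

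Over the 6 comparisons of behaviour groups, camera made 24 list calls with the preset and 2 with an estimated correlation, where oligodendrocyte (-0.364) and potassium (0.0977) lists had an adjusted p of 0.0671. With the mean over all probes of a gene, 2 calls were made, both for blood, and the oligodendrocyte and potassium lists were at -0.336 (0.0659) and 0.0627 (0.0974).

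Without the 3 arrays that stood apart, NAc comparisons with control gave 5 (susceptible) and 2 (unsusceptible) probes, and VTA unsusceptible against control and NAc susceptible against unsusceptible gave 0. No list passed in the comparisons of behaviour groups that were refitted, with NAc blood at 0.976 (0.0568), oligodendrocyte at -0.231 (0.0650) and potassium genes at 0.0821 (0.0650). VTA susceptible against control holds none of these arrays and was not refitted, so its blood call was not tested here. With the dopamine or cortical covariate potassium genes had 0.0719 (0.461) and 0.0801 (0.348).

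Leaving out 1 array in turn gave ranges of 0 to 143 probes in NAc susceptible, 0 to 404 in NAc unsusceptible, 0 to 15 in VTA susceptible and 0 to 270 in VTA unsusceptible against control. NAc susceptible against unsusceptible gave 0 throughout, the VTA 0 to 139, the differences between structures 0 to 1 and 0 to 60, and VTA against NAc 11914 to 12499. NAc blood ranged from 0.948 to 1.10, VTA blood from 0.770 to 1.10, oligodendrocyte from -0.451 to -0.231 and potassium genes from 0.0821 to 0.123, with 1 to 9 list calls. These counts keep the calls of the full fit for comparisons that do not hold the array left out.

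The table of the whole series and the offset of 50, run for probe counts, moved no count by over 1.5 times, nor did the random block of behaviour and number for the differences between structures and VTA against NAc, or quantile normalization per structure for the comparisons within a structure and their lists. With the offset, S100a9 and S100a8 lost their NAc calls (adjusted p 0.0569 and 0.0624). Of the other values, 6527 for genes and 3325 for lists kept direction and side of the threshold, 113 and 49 came to pass it, 100 and 48 ceased to, and 138 and 319 moved. Fry in its mixed form was run in the main fit only, so no mixed call was checked under an alternative. Without background values, the signal over background is unknown, which limits the dim probes.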

Other observations

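No tests were run for this part. The orexin precursor gene Hcrt lay between 7.76 and 7.88 in VTA control pools, but at 12.52 in VTA susceptible pool 3 and at 9.81, 9.67 and 12.10 in VTA unsusceptible pools 1, 2 and 3. VTA unsusceptible pool 3 also had the lowest serotonin neuron list, 8.24, and Tph2 at 6.89. Hypothalamic peptides had list levels of 7.80 ± 0.01, 8.09 ± 0.33 and 8.38 ± 0.42 in VTA control, susceptible and unsusceptible pools (SD, n = 3).

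Lcn2 lay between 7.02 and 7.30 in the control pools of both structures and between 8.53 and 9.02 in all susceptible pools. Unsusceptible pools were divided, with 8.72, 8.97 and 7.33 in the NAc and 8.90, 7.41 and 7.56 in the VTA. In VTA unsusceptible pools 1, 2 and 3, S100a8 lay at 8.57, 7.87 and 7.47, where the highest VTA control was 7.20. S100a9 lay there at 8.22, 7.83 and 7.59, where the highest VTA control was 7.38.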
